A study of Mus musculus with 36 samples.

How the data were processed

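Chromatin carrying the histone variant H2A.Z was measured in livers of adult mice kept under 12 h of light and 12 h of darkness. Livers were collected every 4 h at 6 zeitgeber times (ZT, hours after lights on), starting at ZT2. Wild-type mice (WT) were compared with Bmal1-/- mice (BM), which lack BMAL1, the partner of CLOCK in the transcription factor that drives the circadian clock. Per the labels' protocols, nuclei were crosslinked and digested with micrococcal nuclease, H2A.Z nucleosomes were immunoprecipitated, and mononucleosome fragments were sequenced.

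Per the submitters' processing notes, the tools were CASAVA 1.7 and Bowtie, and the genome build was mm9. The version of Bowtie, the normalization of the signal and the peak caller were not given in the sources used here. The deposited signal table holds H2A.Z signal (coverage) that the authors averaged over sets of CLK:BMAL1 peaks, with 1 profile of 299 positions per library and peak set. The deposited peak table lists 3217 CLK:BMAL1 peaks with their positions, windows of 3 kb and a class of genomic location. No signal of a single peak was used here, because each profile is an average over a whole set. A step of 10 bp between positions was inferred from the window and the number of positions. The row labels of the set of all peaks give 3216 peaks.

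Each library's scale was examined from the values. The search for 1 factor per library used the TSS set and intergenic peaks beyond 10 kb. Signal multiplied by the number of peaks and by the factor came out whole within 0.15 for 100% of TSS positions in every library. The median beyond 10 kb was also 100%. As the factors were fitted to these sets, this is no independent check of them. Outside the search, where chance gives 30%, the median was 71.7% for gene bodies and 36.0% for all peaks. For all peaks it was 0% in BM at ZT10 and ZT14, so the factors rest on the sets they were fitted to. The factors ran from 0.416 to 1.92, a 4.61-fold range. The factor search was tested on simulated data and recovered 5 of 5 known factors. What the factor stands for was not given in the sources used here, so read depth is unknown, and a level compared between libraries rests on the authors' scaling. No row of the signal table was left without a sample.

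The labels gave 4 WT series (replicate numbers 11, 12, 25 and 26) with 1 library at each time, 24 in all, and 2 BM series (numbers 5 and 8) with 6 samples each. BM series 5 gave the 6 BM libraries used, and the 6 samples of BM series 8 were not analysed here. The source names part the samples into 2 sets. The first holds WT series 11 and 12 and BM series 5, and the second holds WT series 25 and 26 among the libraries used. Nothing in the labels says which libraries came from separate animals, so the p-values measure only the spread between these libraries. The deposited values hold no gene-level measurement of Bmal1, so the knockout label was not checked.

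The tests were fixed before the data were examined as fits per peak with a linear or count model. Averaged profiles cannot carry those fits. The tests written for the mean signal over all peaks were used in their place, and the counts of changed peaks, the gene lists and the rule for named genes were not run. That rule would have named each core clock gene with a peak, the 10 largest changes each way and 4 genes per list. Peaks were not assigned to genes, because the gene table at hand is of another assembly than mm9.

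The planned measure was the log2 of the mean signal over the window. Measures of the profile's shape were chosen after the profiles were seen. The flank was the mean of the outermost 25 positions on each side, the shoulder the mean from 150 to 230 bp on both sides of the centre, and the centre the mean within 30 bp of it. Centre fill was the centre above flank divided by the shoulder above flank, so that 0 is a gap down to the flank and 1 is no gap. Enrichment was shoulder divided by flank. Neither ratio depends on the scale factor of a library. Another set, intergenic peaks within 10 kb of a gene, was solved from the other sets and holds 293 peaks.

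Genotypes were compared by exact two-sided permutation of the genotype label over the 30 libraries (593775 assignments), within time (15625), and within time in the first set (729, smallest possible p 0.00137). Rhythms were fitted as a cosinor of period 24 h and tested by 100000 permutations of time in WT and by all 720 orders in BM, where the smallest possible p is 0.0167. The difference of rhythm was tested exactly by moving the BM label within time. Benjamini-Hochberg adjustment covered 25 tests per measure and 12 comparisons of peak classes. In 100 simulated data sets per setting with the real spread of the all-peak window signal, a WT amplitude of 1 SD was called in 83, and its absence in BM in 27. With no effect the calls were 5 and 4. For centre fill these were 83 and 15, and with no effect 2 and 1. At an amplitude of 2 SD the calls were 100 and 64 for window signal, and 100 and 74 for centre fill. Amplitudes between 0 and 1 SD were not simulated. A genotype shift of 0 in centre fill was called in 9 of 100 by the permutation within time. The simulated libraries were drawn independently, with no level shared by a series. These rates therefore do not cover a series that differs in level, and all BM libraries used are of 1 series.

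The alternatives covered the pseudocount, the summary over positions, scaling to equal flanks, each series, library and time left out, the set of samples, the replicate block, another rhythm test and the settings of centre fill. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.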

Results

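H2A.Z nucleosomes were profiled in mouse liver at the sites bound by CLOCK:BMAL1, the transcription factor at the head of the circadian clock. The profiles covered 24 wild-type (WT) libraries, 4 at each of the 6 zeitgeber times, and 6 Bmal1-/- (BM) libraries, 1 at each time. Each library was given as its mean signal over windows of 3 kb around the CLK:BMAL1 peaks, for all peaks and by class of genomic location. The signal is in the authors' scaled units, and its read depth is unknown. No 2 libraries held identical profiles.

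The CLK:BMAL1 peaks had a median width of 309 bp, from 40 to 719 bp. Gene bodies held 1623 peaks of the list (50.5%), most of them with the intron label. Transcription start sites (TSS) held 583 peaks (18.1%). Intergenic sites beyond 10 kb held 717 (22.3%), and intergenic sites within 10 kb held the other 9.14%. The first peak of the list lies in mm9 on chromosome 7 from 52960041 to 52960760 and is a TSS peak. The fifth, in an intron of a gene body, lies on the same chromosome from 52962811 to 52963430. Windows overlapped another window for 630 peaks (19.6%), so part of the signal is shared between peaks.

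In both genotypes H2A.Z formed a pair of shoulders around the bound site with a dip between them. Over all peaks in WT, the mean profile reached 31.7 at -200 bp and 31.6 at 180 bp, and fell to 19.9 at -20 bp. In BM the shoulders stood at the same positions, at 20.6 and 20.4, with a dip of 15.1. The shoulders of a WT library were 382.5 bp ± 13.9 (SD, n = 24) apart over all peaks. At TSS peaks the spacing was 426 bp ± 34.6 (SD, n = 24), and at gene body peaks it was 369 bp ± 18.7 (SD, n = 24).

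**Figure D1:**
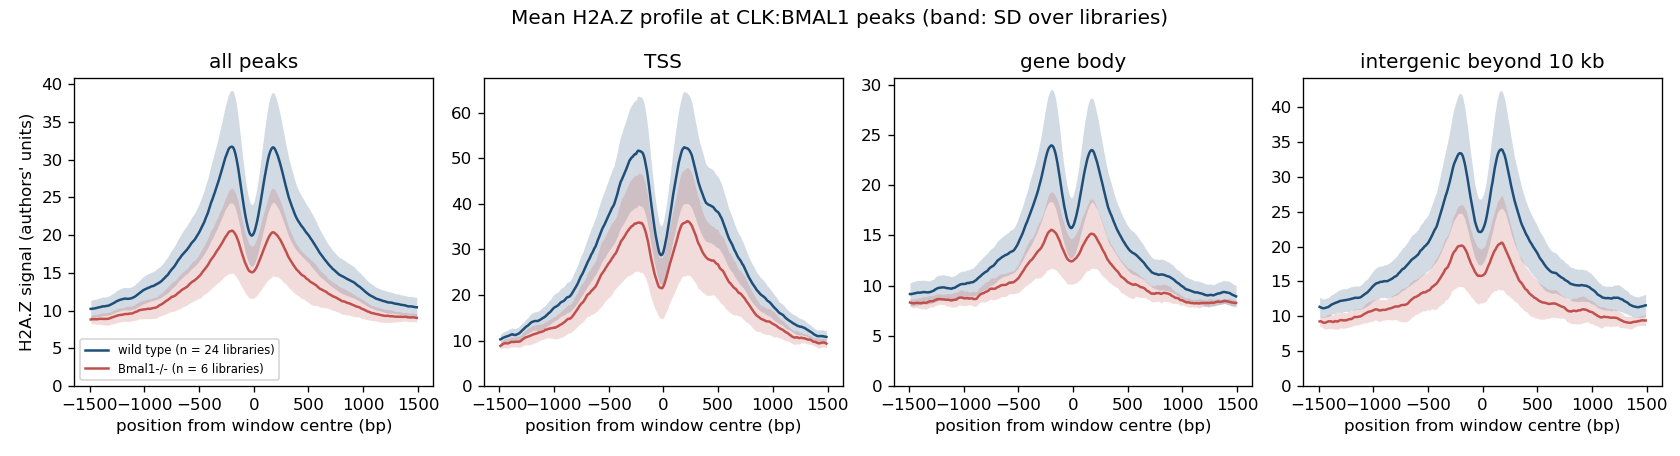
Mean H2A.Z signal in the authors' units against position in bp from the window centre, for all peaks and 3 classes of location. Lines are means and bands are SDs over 24 WT and 6 BM libraries, and over all peaks the left shoulder stands at 31.7 in WT and 20.6 in BM.

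Peaks at TSS carried the most H2A.Z. The mean window signal in WT was 27.5 ± 5.45 (SD, n = 24) at TSS and 13.4 ± 2.16 (SD, n = 24) at gene bodies. Intergenic peaks lay between them, with 18.4 ± 3.54 beyond 10 kb and 18.8 ± 3.49 within 10 kb (SD, n = 24). TSS peaks exceeded gene body peaks 2.04-fold, in 24 of 24 WT libraries (permutation of signs, p = 1e-05, the smallest that 100000 permutations can give). In BM the ratio was 1.89-fold, in 6 of 6 libraries (exact sign permutation p = 0.0312).

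The comparison of WT with BM asks whether H2A.Z at these sites depends on BMAL1. Signal was lower in the BM series in every class of peak. Over all peaks the window signal was 17.6 ± 3.14 (SD, n = 24) in WT and 12.9 ± 2.36 (SD, n = 6) in BM. The log2 difference was -0.44 (SE 0.12), a fold of 0.737, and BM lay below all 4 WT libraries at 6 of 6 times. The difference passed the exact permutation test over libraries (p = 0.00126, adjusted p = 0.00995) and within time (exact p = 0.000256). The log2 difference was -0.47 (SE 0.17) at TSS, -0.36 (SE 0.09) at gene bodies, -0.53 (SE 0.13) at intergenic peaks beyond 10 kb and -0.51 (SE 0.13) at those within 10 kb. Within the first set of samples these were -0.33, -0.22, -0.36 and -0.35 (exact permutation p = 0.00137 each). In each of these 4 classes BM was lowest at 6 of 6 times, and the adjusted exact permutation p ran from 0.00644 to 0.0180. Against the 2 WT series of its own set of samples the all-peak difference was -0.29 (exact permutation p = 0.00137, the smallest possible), and the second set held no BM library among those used.

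The BM libraries used form 1 series. Over the means of the 5 series the exact permutation p was 0.2, the smallest that 5 series allow, and the 4 WT series differed among themselves by up to 0.39 on the log2 scale. Equal flank signal, with each profile divided by its own flank, was a scaling chosen after seeing the data. With it the all-peak difference was -0.21 (exact permutation p = 0.00171) and the TSS difference -0.23 (exact permutation p = 0.00447).

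BM signal was lowered less at gene bodies than at intergenic peaks, a contrast within each library that no scale factor can move. The BM minus WT difference of gene body and intergenic peaks beyond 10 kb was 0.17 on the log2 scale (exact permutation p = 0.000674, adjusted p = 0.00162), with BM highest at 5 of 6 times. Against intergenic peaks within 10 kb it was 0.15 (exact permutation p = 0.0003, adjusted p = 0.00162), with BM highest at 4 of 6 times. Within the first set of samples these were 0.15 (exact p = 0.00137) and 0.13 (exact p = 0.00274). At equal flank signal, where each class is divided by its own flank, gene bodies were no longer the less lowered. The log2 differences were then -0.22 at gene bodies, -0.20 beyond 10 kb and -0.15 within 10 kb. The flank itself was lowered less at gene bodies (log2 difference -0.14) than beyond 10 kb (-0.33) or within 10 kb (-0.36).

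**Figure D2:**
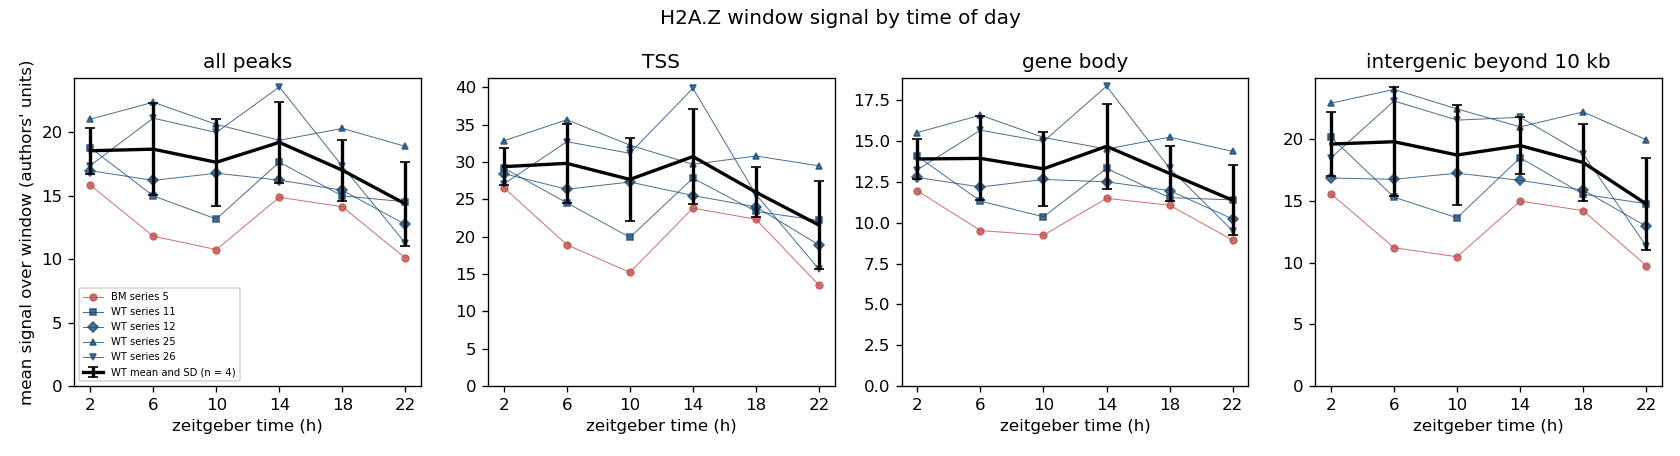
Mean signal over the window in the authors' units against zeitgeber time in h, for all peaks and 3 classes of location. Thin lines are single series, and the thick line is the WT mean with its SD over 4 libraries, and over all peaks the BM series lies below the 4 WT libraries at 6 of 6 times.

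The sampling over the light:dark cycle asks whether H2A.Z follows the time of day. No 24 h rhythm of the window signal was detected. Over all peaks in WT, the means ran from 14.3 ± 3.30 (SD, n = 4) at ZT22 to 19.2 ± 3.18 (SD, n = 4) at ZT14. The cosinor amplitude was 0.13 on the log2 scale (SE 0.08, permutation p = 0.248, adjusted p = 0.730). It was 0.05 in the first set of samples (permutation p = 0.798) and 0.22 in the second (permutation p = 0.0756). At TSS peaks the amplitude was 0.17 (SE 0.08, permutation p = 0.1499). At equal flank signal the all-peak amplitude was 0.08 (permutation p = 0.0460) and the TSS amplitude 0.10 (permutation p = 0.0330), both unadjusted. In BM the all-peak amplitude was 0.06 (SE 0.20, exact permutation p = 0.967), and the rhythms of WT and BM did not differ detectably (exact permutation p = 0.711). ZT06 exceeded ZT18 over all peaks in WT by 0.12 (SE 0.17, exact permutation p = 0.457), and the BM difference was -0.26 from 1 library per time. In WT, ZT06 was the higher in 4 of 4 series (exact sign permutation within series, p = 0.125, the smallest possible). The WT difference was 0.03 without series 25 at ZT06 and 0.22 without series 11 at ZT06, and the WT amplitude ran from 0.03 without ZT22 to 0.21 without ZT10, with no change of call.

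The depth of the dip did vary with the time of day in WT. Centre fill, the centre above flank as a part of the shoulder above flank, was a measure chosen after the profiles were seen. Over all peaks it was lowest at ZT06, 0.430 ± 0.0267 (SD, n = 4), and highest at ZT18, 0.547 ± 0.0464 (SD, n = 4). A cosinor fit gave an amplitude of 0.0613 (SE 0.0111) with its peak at ZT17.9 (permutation p = 0.00014, adjusted p = 0.00175). The amplitude was 0.0787 in the first set of samples (permutation p = 0.00531) and 0.0524 in the second (permutation p = 0.00413).

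The rhythm of centre fill appeared in each class of peak. TSS peaks had an amplitude of 0.0386 (SE 0.00939, adjusted permutation p = 0.007875), gene body peaks 0.0700 (SE 0.0155, adjusted permutation p = 0.00321), and intergenic peaks beyond 10 kb 0.0738 (SE 0.0122, adjusted permutation p = 0.0005). Intergenic peaks within 10 kb had the amplitude 0.104 (SE 0.0217, adjusted permutation p = 0.00321). Within the first set of samples alone the TSS amplitude was 0.0457 (permutation p = 0.0626), and in the second 0.0365 (permutation p = 0.01195). Peak times over all 24 libraries lay between ZT17.3 at TSS and ZT18.2 beyond 10 kb. They were later in the first set of samples than in the second, at ZT19.0 and ZT16.1 over all peaks, ZT18.5 and ZT15.8 at TSS, and ZT19.5 and ZT15.4 at gene bodies, a gap that was not tested. ZT06 was below ZT18 by 0.117 over all peaks in 4 of 4 WT series (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0510), which fails the correction.

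In BM the centre fill over all peaks had an amplitude of 0.0706 (SE 0.0262) with its peak at ZT20.0, against ZT19.0 for WT in the same set. It did not pass the exact permutation test (p = 0.167), whose smallest p for 6 libraries is 0.0167. Of the 6 ways of leaving out 1 library, it passed only without ZT18 (amplitude 0.104, exact permutation p = 0.0167). Over these ways the exact permutation p ran up to 0.433. Without subtraction of the flank the amplitude was 0.0324 (exact permutation p = 0.833), against 0.0579 in WT. The difference of rhythm between WT and BM was 0.0382 (exact permutation p = 0.548), and 0.0221 within the first set of samples (exact permutation p = 0.900). Without the BM library of ZT22 it was 0.0198 (exact permutation p = 0.853). By class, the BM amplitude was 0.0539 at TSS and 0.104 at gene bodies, above the WT values of 0.0386 and 0.0700. At intergenic peaks it was 0.0444 beyond 10 kb and 0.0798 within 10 kb, below the WT values of 0.0738 and 0.104. No class passed in BM (exact permutation p from 0.133 to 0.85).

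**Figure D3:**
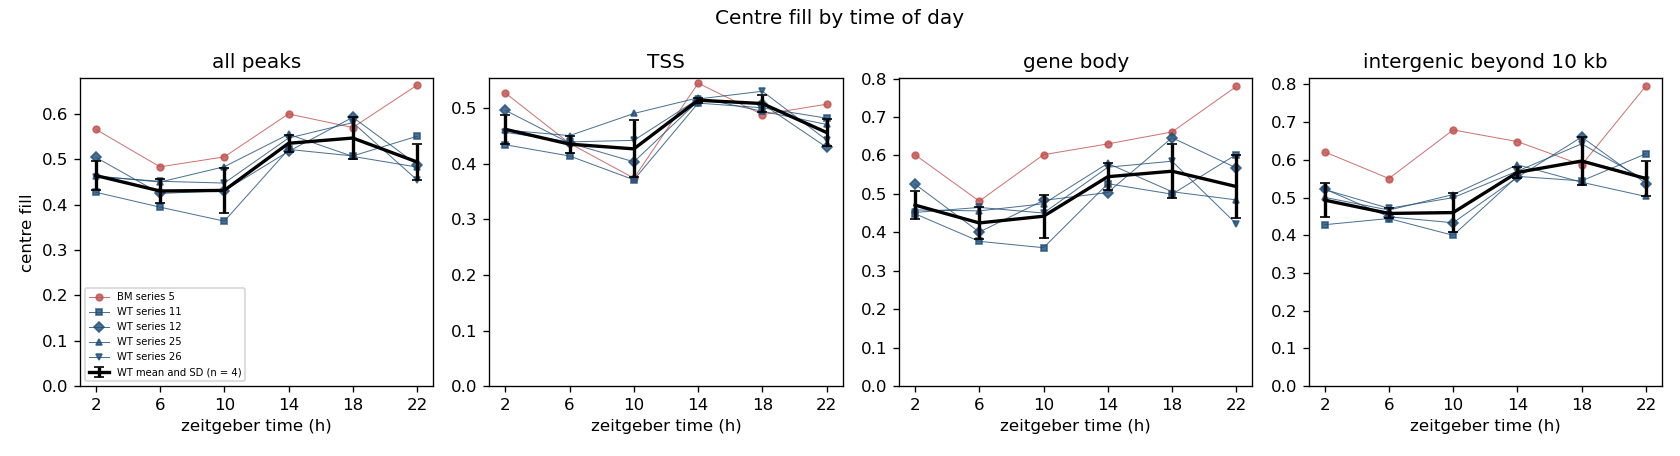
Centre fill, a ratio without unit, against zeitgeber time in h, for all peaks and 3 classes of location. Thin lines are single series, and the thick line is the WT mean with its SD over 4 libraries, and over all peaks this mean is 0.430 at ZT06 and 0.547 at ZT18.

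By centre fill, the dip was shallower in the BM series at gene body and intergenic peaks. Gene body centre fill was 0.493 ± 0.0721 (SD, n = 24) in WT and 0.626 ± 0.0969 (SD, n = 6) in BM, with BM highest at 6 of 6 times (exact permutation p = 0.000859, adjusted p = 0.00321). Intergenic peaks beyond 10 kb had 0.521 ± 0.0669 (SD, n = 24) in WT and 0.647 ± 0.0860 (SD, n = 6) in BM (exact permutation p = 0.000603, adjusted p = 0.00321, BM highest at 5 of 6 times), a difference of 0.126 that was 0.0821 with log2 enrichment, shoulder over flank, as a covariate (permutation p = 0.0347). Those within 10 kb had 0.406 ± 0.104 (SD, n = 24) and 0.596 ± 0.136 (SD, n = 6) (exact permutation p = 0.000669, adjusted p = 0.00321, BM highest at 5 of 6 times). At TSS peaks the values were 0.467 ± 0.0417 (SD, n = 24) in WT and 0.480 ± 0.0638 (SD, n = 6) in BM, a difference of 0.0126 (SE 0.0274, exact permutation p = 0.558). Without subtraction of the flank, centre over shoulder at TSS peaks was higher in BM by 0.0440 (exact permutation p = 0.0132), and the lower BM enrichment alone, at the WT centre fill, would give 0.0348. With log2 enrichment and time as covariates, a fit chosen after seeing the data, TSS centre fill was higher in BM by 0.0388 (permutation p = 0.0193). Within the first set of samples the gene body difference was 0.131 (exact permutation p = 0.00137) and the TSS difference 0.0216 (exact permutation p = 0.132).

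The difference between TSS and gene body peaks was tested itself. TSS minus gene body centre fill was -0.0260 in WT and -0.146 in BM, a change of -0.120 (exact permutation p = 0.000633, adjusted p = 0.00162), with BM lowest at 6 of 6 times. Within the first set of samples it was -0.109 (exact permutation p = 0.00137). Enrichment was lower in BM at gene bodies too, 1.80 ± 0.353 (SD, n = 6) against 2.50 ± 0.404 (SD, n = 24). With log2 gene body enrichment as a covariate the change was -0.0667 (permutation p = 0.0421). These comparisons rest on 1 BM series, and over the means of the 5 series the exact permutation p for gene bodies was 0.2, the smallest possible.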

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

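Of the tests of the 3 patterns below, the difference of BM and WT in window signal, over all libraries and within the first set, was planned, and the fit of the WT time of day with enrichment as a covariate was set out before its result was seen; the others, and the measure centre fill, were chosen after. In 60 groups of 4 WT libraries, 2 held a value far from the others, and chance gives about 1 in 20, or 3. Gene body centre fill at ZT02 was 0.525 in WT series 12, against 0.448 to 0.458 in the others. Centre fill of intergenic peaks within 10 kb at ZT06 was 0.188 in WT series 11, against 0.363 to 0.394 in the others.

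The first pattern is the lower window signal of the BM series. A scaling factor alone is argued against, because log2 of shoulder over flank, which no factor can move, was also lower in BM by more than its error (-0.40, SE 0.14, exact permutation p = 0.00171). Pulldown efficiency that differs between series stays open, since the 4 WT series means spread over a range of 0.39 on the log2 scale. The BM gap of 0.44 is a distance from the WT mean, so the range and the gap are unlike measures. The BM series mean was 3.67, below the WT series means of 3.96 to 4.35. In the set of samples that holds BM, the 2 WT series differed by 0.01 and BM lay 0.29 below them, but 2 series do not measure how far series spread. The Bmal1-/- genotype stays open as well, because the 1 BM series analysed gives a smallest p of 0.2, so genotype and series cannot be told apart.

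The second pattern is the time of day of centre fill in WT. Pulldown enrichment as the whole cause is argued against, since with it as a covariate the amplitude was 0.0743, 1.21 times its value without (permutation p = 2e-05). Other differences between libraries, such as the digestion, were not tested. The profiles hold no sites other than CLK:BMAL1 peaks, so whether the pattern is particular to these sites is unknown. A single set of samples is argued against over all peaks, since the larger permutation p of the 2 sets was 0.00531. At TSS peaks it stays open, as the permutation p in the first set was 0.0626. Dependence on BMAL1 stays open. The difference of rhythm had an exact permutation p of 0.548, and with 1 BM library per time the upper 95% bound on a loss of amplitude, from the t distribution, was 0.0685, above the WT amplitude of 0.0613, so a full loss was not excluded.

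The third pattern is the higher centre fill of the BM series outside TSS, a limit that holds with background subtraction; without it TSS was higher too (0.0440, exact permutation p = 0.0132), of which lower enrichment alone would give 0.0348, and with enrichment and time as covariates so was TSS centre fill (0.0388, permutation p = 0.0193). TSS minus gene body centre fill changed by -0.120 (SE 0.0390, exact permutation p = 0.000633), and by -0.0667 with gene body enrichment as a covariate (permutation p = 0.0421). A level shift of every class stays open all the same, because error from a thin background margin could give this change. Enrichment in BM was 1.80 at gene bodies, against 3.53 at TSS. Error from a thin background margin stays open, since the change in the unsubtracted ratio (-0.0918) cannot decide it: the lower BM enrichment alone would give -0.0500. Low pulldown enrichment as the whole cause stays open, since a thin background margin is itself low enrichment. A linear covariate cannot be taken to remove such error. With enrichment as a covariate the gene body difference was 0.0994 (SE 0.0443, permutation p = 0.0339), 0.750 of its value without. That beyond 10 kb was 0.0821 (SE 0.0366, permutation p = 0.0347), 0.651 of its value without. With time as a further covariate the gene body difference was 0.139 (SE 0.0388, permutation p = 0.00159). Gene body enrichment in BM was below each WT library of the same time, so these fits extend a linear trend beyond the WT values of a time. Enrichment may account for part or all of the pattern, and the single BM series leaves the genotype untested against series.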

How the results depend on the processing

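Chosen after seeing the data were equal flank signal, the median and the log2 mean over positions, single libraries and times left out, tests within time and over series means, and all settings of centre fill. Of 892 comparisons of a result with an alternative, 849 kept direction and side of the threshold, 35 were weaker, 4 stronger and 4 reversed. For a rhythm, a kept direction meant a peak time moved by no more than 6 h. The difference of rhythm has no direction, so for it only the side of the threshold was compared. Over series means the BM minus WT differences of -0.44 in window signal and 0.0810 in centre fill no longer passed, as that test cannot go below 0.2. At equal flank signal the WT amplitudes of 0.0809 over all peaks and 0.10 at TSS passed unadjusted, and the BM amplitude at TSS, never past the threshold, was 0.0188 with its peak over 6 h away; the cause was not tested. With 1 BM library left out, the BM window amplitude ran from 0.00755 to 0.274, and its peak moved by over 6 h without ZT10 (0.127), ZT14 (0.113) or ZT18 (0.00755). The BM centre fill amplitude ran from 0.0506 to 0.104 and passed without ZT18 (0.104, exact permutation p = 0.0167), on 5 libraries. The ZT06 minus ZT18 centre fill in WT ran from -0.137 to -0.0996 with libraries or series left out, where 3 against 3 cannot go below 0.1.

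The WT centre fill amplitude ran from 0.0548 to 0.0705 over 34 ways of leaving out a series, library or time, with permutation p at most 0.00231. The difference of rhythm in centre fill ran from 0.0198 to 0.0539 and did not pass. The all-peak window difference of BM and WT ran from -0.50 to -0.36 over 40, with exact permutation p at most 0.00798. For centre fill it ran from 0.0613 to 0.0973, with p at most 0.0433, and with enrichment as a covariate it was 0.0692 (permutation p = 0.0471). Without background subtraction the BM minus WT difference at TSS was 0.0440 and passed, against 0.0126 with it. TSS minus gene body centre fill, BM minus WT, ran from -0.140 to -0.0947.

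WT series numbers recur across times. Deviations of same-numbered libraries from the mean of their time correlated over 0.1 in 44 of 60 pairs, with a median of 0.793 against -0.489 for other pairs, so series differed in level. Of 24 libraries, 11 correlated best with their own number, more than chance gives with 4 WT series. As 16 pairs were not over 0.1, the numbers were still not taken to pair samples, though pairing is not excluded. The permutations over libraries thus treat libraries of 1 series as independent, which the difference in level between series goes against. With the replicate block the WT window amplitude was 0.13 and that of centre fill 0.0613, with no change of call, and the ZT06 minus ZT18 centre fill was -0.117 with an exact p of 0.125, the smallest that 4 pairs allow. WT and BM share no number. Not run, because the profiles are averages over peaks, were the filter on low peaks, median and quantile scaling over peaks, other thresholds on peaks, 1 peak per gene and the count model.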

Other observations

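The order of the peak list carries structure that no comparison above used. With the list parted into 4 equal stretches, the median peak width was 369 bp in the first and 329 bp in the next, and it was lower again in both later stretches. TSS peaks made up 20.5% of the first stretch (95% Wilson interval 17.9 to 23.4), and their share in the last had an interval of 13.7 to 18.7. Intergenic peaks beyond 10 kb made up 18.8% of the first stretch (16.2 to 21.6) and 24.8% of the last (21.9 to 27.8). What the list is ordered by was not given in the sources used here. Windows overlapped another window for 26.2% of the intergenic peaks within 10 kb and 16.9% of those beyond 10 kb.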
